A study of Mus musculus with 458 samples.

How the data were processed

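Donor-derived haematopoietic stem cells (HSCs) were index sorted, one cell per well, from the bone marrow of transplanted C57BL/6 mice. Single-cell libraries were made with the SMARTer Ultra Low RNA kit, per the labels' protocols. The sorted phenotype was LSK CD150+CD48-CD45.2+, a gate for HSCs in which CD45.2 marks the donor. Each of the 458 deposited samples was 1 cell. The prefix of each cell's title was taken as the name of its mouse, which gave 6 mice, 2 for each of 3 reconstitution types. Replicate numbers were given in accession order and pair no mice.

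The expression table holds RPKM values (reads per kilobase of gene, scaled to the reads of a cell) for 22645 gene symbols, made by the authors. The gene lengths and the read total behind them were not given in the sources used here. TopHat, featureCounts and the mm10 build were used, per the submitters' processing notes, with versions not given in the sources used here. Whole reads could not be recovered from the RPKM values, so no count model was fitted. A second deposited table gives for each cell the count of mapped reads, the count of detected genes and the percent of reads on the mitochondrial chromosome, per the file headers. It also gives a mouse, a recorded sex and a reconstitution status, and does not say whether the sex is that of donor or recipient. The authors' count of detected genes exceeded the number of genes above 1 RPKM by a median of 8 per cell (range 1 to 22). Values above 0 include traces far below 1 RPKM, so a share of cells above 0 is no share of expressing cells, and the shares at 1 RPKM or more are given for the leading genes. No filter on cells was applied. No doublet caller was run on these plate-sorted cells. No 2 cells had identical values, and the highest correlation between cells was 0.613. Gene positions came from GENCODE M21 on the same genome build, matched by symbol for 21039 genes and through an older symbol for 1254 more. The file uses some older symbols, such as Sfpi1 for Spi1 and Darc for Ackr1. Genes at 0 are described as listed at 0, since Gapdh was also at 0 in some cells of every mouse. Actb, in contrast, was at 0 in 0 of the 458 cells.

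Cells are not replicates, so RPKM was averaged over the cells of each mouse and the 6 mouse means were tested as log2(mean RPKM + 1). A fold change is on that scale, which understates the change of low genes. Genes with a mean of at least 1 RPKM in at least 2 of the 6 mice were tested, 11337 in all. The program limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 6 mice with a shared, intensity-trended variance (eBayes). Benjamini-Hochberg adjustment was applied over the genes of a contrast with a threshold of 0.05. The contrasts were PLT minus MUL, PEM minus MUL, PLT minus PEM, and the mean of PLT and PEM minus MUL. The p-values rest on the spread between the mice of a group, with 3 residual degrees of freedom per gene. That spread was moderated over genes, which gave 8.33 degrees of freedom in total. Both MUL mice came from 1 experiment and every other mouse from an experiment of its own. Experiment and group therefore cannot be told apart, and experiment was no covariate. The spread of the MUL pair holds no difference between experiments, while that of the PEM and PLT pairs does. An exact two-sided permutation test of 2 mice against 2 cannot go below p = 0.33, so single quantities are given as values without a test.

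Of 23 gene lists fixed before the data were examined, 17 had at least 5 tested genes. These were tested with limma's camera at its preset inter-gene correlation of 0.01, with adjustment over the lists of a contrast. Camera with an estimated correlation and fry were run as alternatives. The lists of B cell, T and NK cell, mast cell and basophil, endothelial and stromal, mature erythroid and sex-linked genes had fewer tested genes and are given as values. Named genes were chosen in each pairwise contrast and direction. These were up to 12 with the largest change past the threshold and without overlap between mice, filled up to 10 with the smallest unadjusted p. A further 22 genes of HSC and lineage identity were kept in every contrast whatever their value. Also named were at most 4 members of a list that passed over all genes or over the list alone. Adjustment over the list alone does not cover the number of lists and contrasts screened. Predicted genes were counted and not described, and some named genes are not reported here. For the markers of mature cells, a cell was counted where at least 3 markers of a list were above 0. Shares of cells have exact Clopper-Pearson 95% intervals that cover counting error only, and a share of 0 allows up to 3 counts of the total.

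The gene test and camera were tested on simulated data. The residuals used for this have 3 degrees of freedom, so all simulated genes share 3 patterns of noise. The correlation between genes seen in these few mice was thus taken as true, and may differ from the real one. Noise was drawn from the real residuals of the 6 mice, which keeps the correlation between genes, in 40 draws without any difference between groups and again with 200 genes, drawn from those whose mean log2 value was that of more than 10 RPKM, changed by known folds. Alternatives covered the pseudocount, the filters on genes and cells, the way cells were averaged, the number of cells, the normalization between mice, the plate, the variance model, the mice in the fit and each mouse left out in turn. Another 3 were chosen after seeing the data: cells with mature markers left out, only cells with 1800 to 3000 detected genes, and the mean of log2 values with quantile normalization. Figures were drawn with matplotlib 3.10.9.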

Results

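Single HSCs positive for Vwf had been transplanted into mice, and the recipients were followed over 16 weeks for the blood lineages that the transplanted cell replenished. In multilineage (MUL) mice the clone gave all lineages, in PEM mice platelets, erythrocytes and myeloid cells, and in PLT mice platelets alone. The data ask how the transcriptomes of the donor-derived HSCs in the marrow differ between these fates. The 458 cells comprised 163 MUL, 118 PEM and 177 PLT cells, with 25 cells in PEM mouse 2 and 78 to 93 in each other mouse. Cells had a median of 4.9 M mapped reads, with a range of 1.3 to 17.3 M. The median number of genes above 0 per cell was 4716 ± 504 in MUL, 5384 ± 928 in PEM and 4502 ± 522 in PLT mice (mean ± SD, n = 2 mice each), and these means differed by less than the SD of the PEM mice. The authors' count of detected genes was 2381 ± 243 in MUL, 2969 ± 307 in PEM and 2233 ± 514 in PLT mice, with both PEM mice above the other 4. The median percent of reads on the mitochondrial chromosome, as given by the authors, was 5.7 ± 0.512 in MUL, 4.02 ± 0.0147 in PEM and 6.55 ± 0.197 in PLT mice, without overlap between the groups. The 50 highest genes of a cell took a median of 21.7% ± 1.88, 21.5% ± 0.941 and 24.8% ± 1.13 of its RPKM in MUL, PEM and PLT mice. Median depth lay between 4.28 and 5.32 M reads in every mouse, but within PEM mouse 2 the plates had medians of 3.2 and 12.2 M.

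Vwf itself, the gene of von Willebrand factor whose expression marked the transplanted cells, had its lowest values in the multilineage mice. Its mean RPKM was 5.46 ± 4.34 in MUL, 24.1 ± 0.76 in PEM and 16.8 ± 2.35 in PLT mice (SD, n = 2 each). It was above 0 in 15.4% (95% interval 8.21 to 25.3) and 37.6% (27.4 to 48.8) of the cells of the MUL mice. The shares were 91.4% and 68% in the PEM mice and 73.1% and 73.8% in the PLT mice. At 1 RPKM or more, the mean share of cells was 13.4% in MUL, 47.4% in PEM and 34.9% in PLT. In limma these differences did not pass adjustment (adjusted p = 0.592 for PLT minus MUL and 0.868 for PEM minus MUL).

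Markers of mature blood cells were unevenly spread over the mice. At least 3 mature erythroid markers were above 0 in 36% of the cells of PEM mouse 2 and in 3.23% to 17.9% of the cells of the other mice. At least 3 neutrophil markers were above 0 in 24% of the cells of PEM mouse 2, 14% of PLT mouse 1, 11.8% of MUL mouse 2 and 0% to 2.38% in the other mice. S100a8, the gene of a calcium-binding protein abundant in neutrophils, reached a mean of 9322 RPKM in PEM mouse 2 against 23 in PEM mouse 1. For macrophage and monocyte markers the share ran from 0% in MUL mouse 1 to 10.8% in PEM mouse 1. T and NK cell markers were met in 0% to 9.68% of cells, the highest share also in PEM mouse 1. These shares count values above 0, traces included, and PEM mouse 1 had the highest median of genes above 0 (6040). Summed mean RPKM ranked the mice otherwise. For T and NK cell markers it was highest in MUL mouse 1, at 222 against 127 in PEM mouse 1. For macrophage and monocyte markers it was highest in PEM mouse 2, at 159 against 85.9 in PEM mouse 1. B cell markers were met in 12% of the cells of PEM mouse 2 and in none elsewhere. Endothelial and stromal markers were met in at most 1.28% of the cells of any mouse, and mast cell and basophil markers in none. The neutrophil list was not called between groups (camera adjusted p = 0.438 for PLT minus MUL, 0.177 for PEM minus MUL and 0.772 for PLT minus PEM).

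The comparison of PLT with MUL asks what sets HSCs that replenish platelets alone apart from multilineage HSCs. Ctla2b, which encodes a cysteine protease inhibitor first found in T cells (chromosome 13, 60895350 to 60897447, minus strand, mm10), fell by 4.29 ± 0.38 (SE) on the log2 scale in PLT. Its mean RPKM was 408 ± 65.9 in MUL, 81.9 ± 5.5 in PEM and 20.1 ± 5.31 in PLT mice (SD, n = 2 each). It was at 1 RPKM or more in a mean of 88.6% of MUL, 71.5% of PEM and 23% of PLT cells. Its close paralog Ctla2a, chosen after its values were seen, had means of 401 ± 163, 158 ± 5.62 and 46.6 ± 46.6 RPKM, and reads of such paralogs can be shared. Ctla2b was the 1 gene of 11337 past the threshold (limma, adjusted p = 0.0289). An unadjusted p under 0.05 was found for 953 genes, 277 higher and 676 lower in PLT, where chance gives 567. The mouse means were not normalized to each other. The median log2 fold change over all genes was -0.18, a shift that favours lower genes in this split. The 2 mice of PLT lay wholly to one side of those of MUL for 39.7% of genes, against 33.3% by chance. Leaving out any 1 of the 6 mice ended the Ctla2b call (adjusted p = 0.0573 to 0.541), as did 8 other settings, among them the mean of log2 values over cells (0.217) and 25 cells per mouse (0.453), while it stayed lower in PLT. In simulated mice without a difference, 2 of 40 draws called any gene in this contrast, with up to 358 genes in a draw. The groups were also separate experiments, so a difference between groups cannot be told apart from one between experiments, here and in the other comparisons with MUL.

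**Figure D1:**
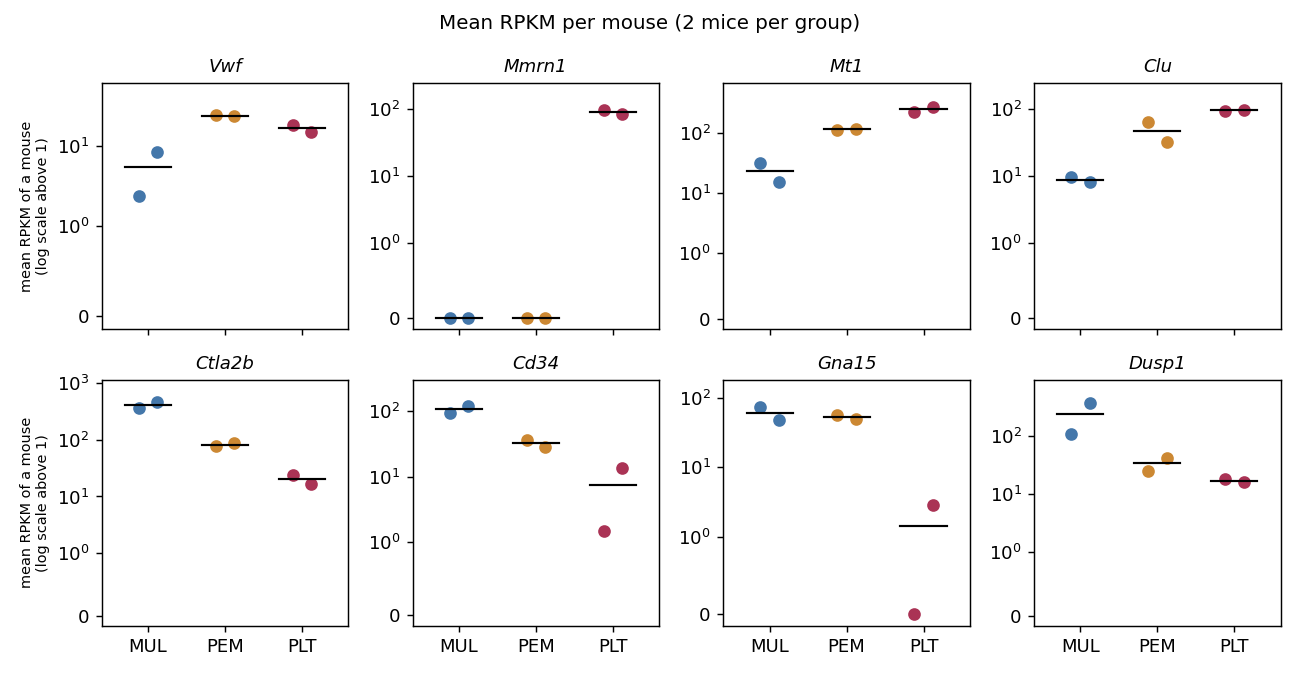
Mean RPKM of each mouse (points, n = 2 mice per group) and the group mean (bar) for 8 named genes, on an axis that is logarithmic above 1 RPKM and linear below. Ctla2b falls from 408 RPKM in MUL to 20.1 in PLT mice, and Mmrn1 lies at 97.5 and 84.4 RPKM in the PLT mice and at or near 0 elsewhere.

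Mmrn1, the gene of multimerin 1, a protein of platelet granules (chromosome 6, 60924976 to 60989378, plus strand), had the smallest p of the genes that were higher in PLT. Its means were 97.5 and 84.4 RPKM in the PLT mice. It was listed at 0 in every cell of both MUL mice and of PEM mouse 1, and was above 0 in 1 of the 25 cells of PEM mouse 2. In the PLT mice it was above 0 in 83.9% (95% interval 74.8 to 90.7) and 90.5% (82.1 to 95.8) of cells, and at 1 RPKM or more in 28 of 93 and 36 of 84 cells. For cells listed above 0, and for counting error only, the 0 of 78 and 0 of 85 cells of the MUL mice allow shares of up to 3.85% and 3.53%. Mmrn1 did not pass adjustment (limma, adjusted p = 0.0883), but passed in 3 of 19 alternatives (range 0.000438 to 0.932). These were a pseudocount of 10 (adjusted p = 0.049), quantile normalization (0.0292) and the mean of log2 values with quantile normalization (0.000438).

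Other genes that were higher in PLT than in MUL also missed the threshold (adjusted p = 0.102 to 0.442 for the 9 others named). Erdr1 passed in 4 and Mt1 in 3 of 22 alternatives. Mt1, a metallothionein gene, had a mean of 23.3 ± 11.7 RPKM in MUL and 256 ± 34.6 in PLT mice. Its neighbour Mt2 was listed at 0 in MUL and had 14.3 and 18.9 RPKM in the PLT mice. Clu, the gene of the secreted chaperone clusterin, had 8.89 ± 1.06 against 96.1 ± 4.39 RPKM, and Gkn3 had 4.03 ± 1.3 against 120 ± 18.6. Erdr1 had 3.29 and 0 RPKM in the MUL mice and 102 and 308 in the PLT mice. Ppbp, which encodes a platelet chemokine, was listed at 0 in MUL and had 11.2 and 31.9 RPKM in the PLT mice. Gpx8 and Dpy19l2 were likewise listed at 0 in MUL, with 23.4 and 13.9 RPKM and 10.6 and 8.12 RPKM in the PLT mice. Bola2 had 60.1 ± 10.2 against 187 ± 17.5 RPKM.

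Genes that were lower in PLT than in MUL did not pass adjustment apart from Ctla2b (adjusted p = 0.199 to 0.289 for the 9 others named by the smallest p). Gna15, the gene of a G protein alpha subunit of blood cells, had 72.1 and 47.2 RPKM in the MUL mice and 0 and 2.87 in the PLT mice. Ccl3, a chemokine gene, had 28.4 and 22.4 RPKM in the MUL mice and was listed at 0 in PLT. Tsc22d3, a glucocorticoid-induced gene, had 715 ± 380 against 92.1 ± 41.1 RPKM, and the lysosomal protease gene Ctsd 176 ± 57.3 against 24 ± 15.6. Xlr4a, Trib3, Rnf135 and Cby1 had means of 65.9, 28.3, 71.7 and 33.8 RPKM in MUL against 3.77, 0.159, 4.19 and 2.33 in PLT. Cd34, a surface marker that is low on the most primitive mouse HSCs, had 109 ± 18.3 against 7.46 ± 8.46 RPKM (adjusted p = 0.342). It was above 0 in 69.2% and 83.5% of the cells of the MUL mice and in 3.23% and 26.2% of those of the PLT mice.

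Of the remaining genes fixed for description, Flt3, a receptor of lymphoid-primed progenitors, had 1.89 and 13.2 RPKM in the MUL mice and was listed at 0 in PLT. Itga2b had 14.9 ± 11.8 RPKM in MUL against 1.79 ± 1.27 in PLT, and Kit 90.5 ± 25.8 against 44.5 ± 20.2. Slamf1 (CD150), which was used in the sort, had 12.1 ± 11.1 against 56.7 ± 30.6 RPKM (adjusted p = 0.495 to 0.594 for these 4). Pf4, Gp1ba, Selp, Ly6a, Cdkn1c, Gata1, Klf1, Mki67, Ptprc, Procr, Hlf and Mecom had adjusted p of 0.614 to 0.984. Cd48, used to exclude cells in the sort, was above 0 in at most 3.85% of the cells of any mouse. Dntt and Mpo were listed at 0 in all cells.

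Among the lists, preset camera called 5 of 17 in PLT minus MUL, 4 higher and 1 lower. None was called with an estimated correlation (lowest adjusted p = 0.292) or with fry (lowest adjusted p = 0.259). No list with a known shift was simulated, so the power of these 2 tests is not known. In any contrast, a list that they did not call may still be shifted. In simulated mice with no difference between groups the preset test called a mean of 5.68 lists and the estimated one 0 in every draw. The preset count is therefore of the size that this simulated noise gave. Only counts were compared, not the p of a given list. The HSC ageing-associated genes had a median log2 fold change of 1.14, with 17 of 23 members higher (adjusted p = 0.292 with an estimated correlation). Over all genes 0 members passed, and 9 passed adjusted over the list alone, among them Mt1, Clu, Mt2 and Plscr2. The median was 0.71 without MUL mouse 1, 0.73 without PLT mouse 1 and 1.78 without PLT mouse 2. Ribosomal protein genes had a median of 0.52 with 75 of 81 members higher, and oxidative phosphorylation genes 0.62 with 70 of 85 higher (adjusted p = 0.556 for each with an estimated correlation). PLT mouse 2 carried most of both shifts, with medians of 0.25 and 0.22 when it was left out, against 0.76 and 1.02 without PLT mouse 1. The mitochondrial share of reads was also higher in PLT, at 6.55% against 5.7%. In both lists 0 members passed over all genes or adjusted over the list alone. The median of all genes was -0.18, and 0.03 after quantile normalization and -0.04 after median-ratio scaling, and the called lists kept their direction under both. Megakaryocyte-platelet genes had a median of 0.26, with 15 members higher and 12 lower (adjusted p = 0.53 with an estimated correlation). Of these 27, 4 passed adjusted over the list alone: Mmrn1, Clu and Ppbp were higher, and Nfe2, a transcription factor of megakaryocytes, was lower at 163 ± 59.3 RPKM against 427 ± 129. Clu, Vwf, Selp, Itgb3 and Trpc6 were placed in both the ageing and the megakaryocyte-platelet list, so these lists are not independent. The megakaryocyte-platelet call was lost with quantile normalization and median-ratio scaling (preset adjusted p = 0.0596 and 0.0563), and without PLT mouse 1 the preset test called 10 lists. It was also lost without MUL mouse 2 or PLT mouse 2, where the median turned to -0.067 and -0.14 (preset adjusted p = 0.33 and 0.715), and the median was 0.71 without MUL mouse 1 and 0.58 without PLT mouse 1.

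The immediate early and dissociation stress genes had a median log2 fold change of -1.77 in PLT minus MUL, with 13 of 16 members lower (adjusted p = 0.292 with an estimated correlation). Dusp1, a phosphatase gene induced within minutes of stimulation, and Fos passed adjusted over the list alone. Neither passed over all genes (limma, adjusted p = 0.289 and 0.471). Dusp1 had 242 ± 187 RPKM in MUL against 16.9 ± 1.19 in PLT, and Fos 41.1 and 9.04 in the MUL mice against 0 and 0.401 in the PLT mice. The myeloid list was not called (preset adjusted p = 0.0707), but 2 of its members were lower in PLT adjusted over the list alone. These were Sfpi1, the gene of the myeloid transcription factor PU.1, at 7.73 ± 1.86 against 45.9 ± 9.59 RPKM, and Csf3r at 1.86 ± 0.642 against 21 ± 6.1. Over all genes neither passed (limma, adjusted p = 0.378 and 0.471). Cd34 was the 1 of 27 HSC self-renewal genes that passed adjusted over the list alone, and that list was not called (preset adjusted p = 0.656). The lymphoid, erythroid, quiescence, S phase, G2-M phase, interferon response, antigen presentation, glycolysis and hypoxia, and macrophage and monocyte lists were not called either (preset adjusted p = 0.0536 to 0.853). For S phase genes the median of -0.17 and the mean of 0.04 differed in sign.

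**Figure D2:**
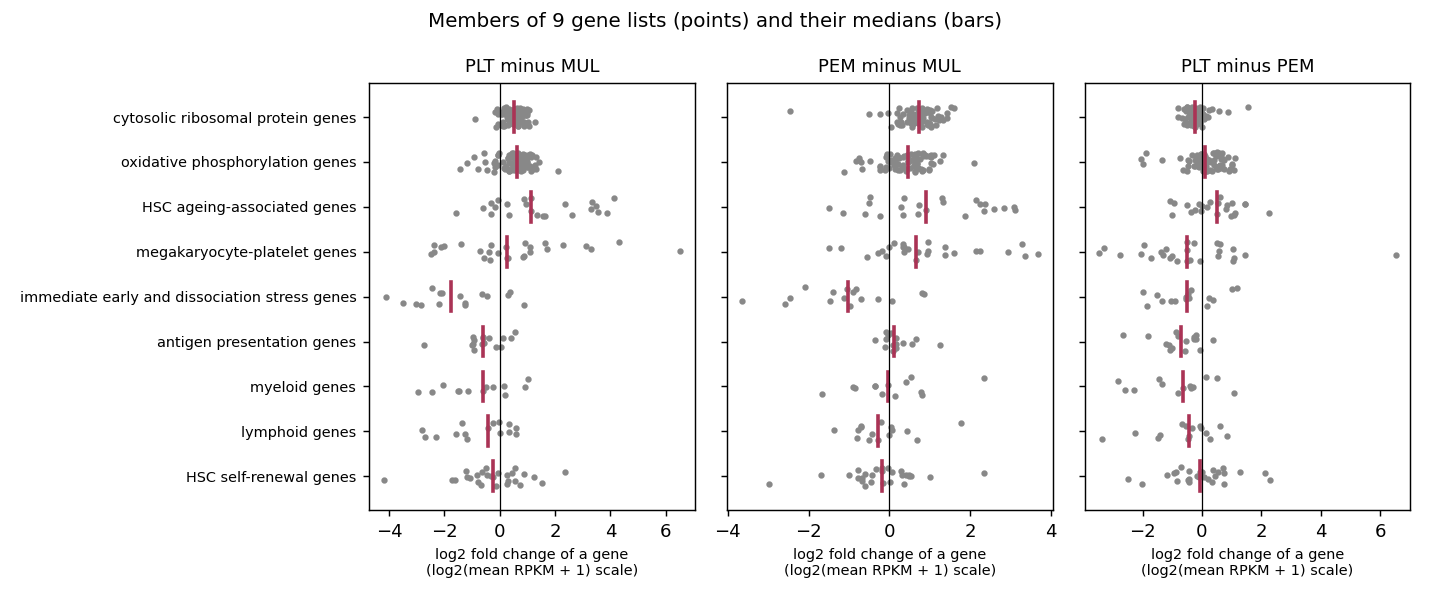
Log2 fold changes of the members of 9 gene lists (points) with the list median (bar) in the 3 pairwise contrasts, each point 1 gene on the log2(mean RPKM + 1) scale. Ribosomal protein genes have medians of 0.52 in PLT minus MUL and 0.74 in PEM minus MUL, and the immediate early list has medians of -1.77 and -1.01.

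The comparison of PEM with MUL asks what accompanies the absence of lymphoid output while erythroid and myeloid output is kept. No gene passed the threshold in limma, and 634 had an unadjusted p under 0.05 where chance gives 567. The smallest p among lower genes was that of Emcn, the gene of endomucin, a surface sialomucin of HSCs and endothelium. It had 62.7 and 56.6 RPKM in the MUL mice and was listed at 0 in both PEM mice (adjusted p = 0.366). Ccl3 and Capsl were also listed at 0 in PEM, and Capsl had 33 and 21.8 RPKM in the MUL mice. Ctla2b had 408 ± 65.9 RPKM in MUL and 81.9 ± 5.5 in PEM, a log2 fold change of -2.30 ± 0.38 (SE; adjusted p = 0.77). Tcte2, Zfp661, Jmjd7, Tmem74 and Clcf1 lay between 4.42 and 18.7 RPKM in the MUL mice and at most at 0.116 in the PEM mice. The smallest p among higher genes was that of Erdr1, with 91.6 and 175 RPKM in the PEM mice (adjusted p = 0.366). Mt1 followed with 118 ± 2.91 RPKM in PEM against 23.3 ± 11.7 in MUL, Smim4 with 190 ± 15 against 47.9 ± 3.26, the HSC and progenitor gene Plac8 with 323 ± 40.5 against 89.9 ± 7.45 and Lst1 with 265 ± 10.1 against 61.8 ± 7.38. Ccne1, a cyclin of the G1 to S transition, had 41.7 ± 37.5 against 0.909 ± 1.05 RPKM, and Darc 24.1 and 40.1 in the PEM mice against 3.32 and 0 in the MUL mice. Pf4, a platelet chemokine gene, was at 419 and 1382 RPKM in the PEM mice and 174 and 19.4 in the MUL mice. Slamf1 had 53.4 ± 17.6 against 12.1 ± 11.1 RPKM and Cd34 32.7 ± 5.92 against 109 ± 18.3 (adjusted p = 0.868 for each, as for the higher genes named after Erdr1).

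Preset camera called 6 lists in PEM minus MUL, 5 higher and 1 lower, and none with an estimated correlation (lowest adjusted p = 0.252) or with fry (lowest adjusted p = 0.29). Simulated mice without a difference gave a mean of 5.4 preset calls. Ribosomal protein genes had a median log2 fold change of 0.74 with 77 of 81 members higher (adjusted p = 0.409 with an estimated correlation). Rpl38, Rpl36 and Rps29 passed adjusted over the list alone, and Rpl38 had 961 ± 26.5 RPKM in PEM and 323 ± 72.9 in MUL. Oxidative phosphorylation genes had a median of 0.47 with 68 of 85 higher, and S phase genes 0.59 with 20 of 24 higher (adjusted p = 0.673 for each with an estimated correlation). The mitochondrial share of reads was lower in PEM, at 4.02% against 5.7%, and the count of detected genes higher. The ageing-associated list had a median of 0.92 with 17 of 23 higher, and Mt1, Clu and Mt2 passed adjusted over the list alone. In cells with 1800 to 3000 detected genes, Clu had a log2 fold change of -1.58, of the other sign. The megakaryocyte-platelet list had a median of 0.66 with 21 of 27 higher and 0 members passing either way. This median was 1.1 without MUL mouse 1, 0.27 without MUL mouse 2 and 1.0 without PEM mouse 2, and that of the S phase list 0.92 without MUL mouse 1 and 0.28 without MUL mouse 2. The immediate early list had a median of -1.01 with 13 of 16 lower, and Dusp1 and Fos passed adjusted over the list alone (adjusted p = 0.252 for each of these 3 lists with an estimated correlation). PEM mouse 2, with the erythroid and neutrophil transcripts described above, is 1 of the 2 PEM mice. Erythroid, myeloid and lymphoid lists were not called (preset adjusted p = 0.155, 0.756 and 0.46), nor were the other lists (0.155 to 0.756). For myeloid genes the median of -0.05 and the mean of 0.05 differed in sign.

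The comparison of PLT with PEM sets the platelet-only fate against the fate that also gives erythroid and myeloid cells. No gene passed in limma, and 949 had an unadjusted p under 0.05 where chance gives 567, with 282 of them higher in PLT and 667 lower. The median log2 fold change over all genes was -0.13 here, which favours lower genes in this split. In simulated mice without a difference, 4 of 40 draws called any gene here, with up to 3335 genes in a draw. Mmrn1 had the smallest p (adjusted p = 0.177) and passed in 1 of 19 alternatives, the mean of log2 values with quantile normalization (0.00109, range 0.00109 to 0.88), and the other genes named here by their p had an adjusted p of 0.539. Among the genes that were lower in PLT, Gna15 had 0 and 2.87 RPKM in the PLT mice against 56.3 and 49.4 in the PEM mice. Sfpi1 had 7.73 ± 1.86 RPKM in PLT against 61 ± 8.15 in PEM, the cyclin gene Ccnd3 15.5 ± 2.07 against 92.8 ± 17.9, Coro1a 51.7 ± 2.3 against 241 ± 14.6 and Fermt3 54.5 ± 3.52 against 217 ± 13.1. Ctla2b had 20.1 ± 5.31 against 81.9 ± 5.5 RPKM. The lysosomal genes Ctsd and Man2b1 had 24 ± 15.6 against 194 ± 0.275 and 4.83 ± 0.0367 against 44.9 ± 8.07 RPKM. Tgfbi had 0.313 and 0 RPKM in the PLT mice against 30.4 and 21.2 in the PEM mice, and Ifi27l2a was listed at 0 in PLT against 17.3 and 26.4. Itga2b, the platelet integrin CD41, was lower in PLT, at 1.79 ± 1.27 RPKM against 24.9 ± 0.323, and passed adjusted over the megakaryocyte-platelet list alone with Mmrn1. Higher in PLT were Gkn3 at 120 ± 18.6 against 8.42 ± 7.15 RPKM, Tubb5 at 2773 ± 251 against 1206 ± 17.1, Calm2 at 3339 ± 190 against 1594 ± 54.2 and Twf1 at 439 ± 94.4 against 137 ± 54.3. Lactb had 16.7 ± 0.519 against 0.54 ± 0.0273 RPKM. Emcn, Capsl and Dpy19l2 were listed at 0 in both PEM mice, and Emcn had 11.1 and 40.7 RPKM in the PLT mice.

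Preset camera called 7 lists in PLT minus PEM, 2 higher and 5 lower, against a mean of 5.78 in simulated mice without a difference. None was called with an estimated correlation (lowest adjusted p = 0.823) or with fry (lowest adjusted p = 0.68). Antigen presentation genes had a median log2 fold change of -0.69 with 15 of 16 members lower, S phase genes -0.62 with 20 of 24 lower and interferon response genes -0.57 with 19 of 24 lower. Myeloid genes had a median of -0.63 with 10 of 13 lower, and Sfpi1 and Csf3r passed adjusted over the list alone. Ribosomal protein genes had a median of -0.23 with 66 of 81 lower, beside a median of -0.13 over all genes. Oxidative phosphorylation genes had a median of 0.12 with 58 of 85 higher and ageing-associated genes 0.50 with 15 of 23 higher (adjusted p = 0.823 for each of these 7 lists with an estimated correlation). Beside these lists, PLT mice had a mitochondrial share of reads of 6.55% against 4.02% in PEM, and 2233 detected genes per cell against 2969. Single mice decided several of these medians, and each of the 7 lists lost its preset call without at least 1 mouse. With PLT mouse 1 left out the ribosomal median turned to 0.031, and the S phase, oxidative phosphorylation and ageing-associated medians were -0.085, 0.54 and 0.19. With PLT mouse 2 left out the oxidative phosphorylation median turned to -0.17, and the antigen presentation, S phase, ribosomal and ageing-associated medians were -0.30, -1.15, -0.52 and 0.75. With PEM mouse 2 left out the ageing-associated median turned to -0.047 and the antigen presentation median was -0.41, and with PEM mouse 1 left out the oxidative phosphorylation median was 0.19. Without PEM mouse 2, 3 lists were called, 3 higher and 0 lower: the oxidative phosphorylation, G2-M phase and neutrophil lists. Without PLT mouse 2, 3 were called as well, the ageing-associated list higher and the S phase and ribosomal protein lists lower. The 10 other lists were not called over all mice (preset adjusted p = 0.052 to 0.996). Of these, the G2-M phase and the macrophage and monocyte lists (0.631 for each) had a median or mean of the other sign than the test.

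The mean of PLT and PEM was also compared with MUL. A change in PLT alone or in PEM alone can move this contrast, so it does not show what both fates share. Mmrn1, for example, was at or near 0 in PEM. No gene passed in limma, and 696 had an unadjusted p under 0.05 where chance gives 567. The lowest adjusted p was 0.0742, for Ctla2b with a log2 fold change of -3.29 ± 0.33 (SE). Erdr1 followed among higher genes (6.19 ± 0.70, adjusted p = 0.0925), with Mt1 at 2.93 ± 0.38 and Ccl3 among lower genes (adjusted p = 0.137 for each). The HSC self-renewal genes Procr, Hlf and Mecom had log2 fold changes of -0.21 ± 0.57, -0.42 ± 0.47 and -0.33 ± 0.48 (SE), all within their errors. Preset camera called 6 lists, 5 higher and 1 lower, against a mean of 5.12 in simulated mice without a difference. None was called with an estimated correlation (lowest adjusted p = 0.215) or with fry (lowest adjusted p = 0.26). The ageing-associated list had a median log2 fold change of 1.05 with 18 of 23 members higher, of which 9 passed adjusted over the list alone. The immediate early list had a median of -1.42 with 12 of 16 lower, of which Dusp1, Fos and Zfp36 passed adjusted over the list alone. The megakaryocyte-platelet list had a median of 0.40 with 18 of 27 higher, of which Mmrn1, Clu and Ppbp passed adjusted over the list alone (adjusted p = 0.215 for each of these 3 lists with an estimated correlation). Ribosomal protein genes had a median of 0.63 with 77 of 81 higher, oxidative phosphorylation genes 0.56 with 70 of 85 higher and S phase genes 0.34 with 17 of 24 higher (adjusted p = 0.396, 0.447 and 0.797 with an estimated correlation). The megakaryocyte-platelet median was 0.74 without MUL mouse 1 and turned to -0.015 without MUL mouse 2, where its call was lost (preset adjusted p = 0.0773), and the oxidative phosphorylation median was 0.32 without PLT mouse 2. The S phase call was lost without MUL mouse 2, PEM mouse 2 or PLT mouse 2, with medians of 0.061, 0.12 and 0.12, and the median was 0.54 without MUL mouse 1 and 0.75 without PLT mouse 1. The other 11 lists were not called (preset adjusted p = 0.126 to 0.825), and of these the erythroid and interferon response lists had medians of the other sign than the test.

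In simulated data for PLT minus MUL over 11337 genes, limma recovered 3.75% of genes changed 2-fold, 22.6% of those changed 4-fold, 63.7% of those changed 16-fold and 79.7% of those changed 64-fold, so smaller differences were mostly not detectable with 2 mice per group. Beside these 3393 calls, 1118 of 445480 unchanged genes were called, 24.8% of all calls pooled over the 40 draws. They came from 9 of the 40 draws, with up to 542 in 1 draw. The pooled share is therefore not the mean share per draw, which the threshold of 0.05 concerns.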

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

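A signal that the recorded data would not lead to was met outside the main comparisons. PLT mouse 2 was recorded as female, yet Ddx3y, a Y-linked gene, was above 0 in 73.8% of its cells, with a mean of 36.5 RPKM. Eif2s3y, also Y-linked, had 84.8 RPKM in that mouse, and Xist, the RNA of the inactive X chromosome, 0.0237 RPKM. PEM mouse 2, the other mouse recorded as female, had Ddx3y above 0 in 4% of its cells and Xist at 30.7 RPKM. The 4 mice recorded as male had Ddx3y above 0 in 62.8% to 87.1% of cells. The cells were donor-derived, and the record does not say whether the sex is that of donor or recipient. A recorded recipient sex would be no conflict. Sex-linked genes also differed within the PEM pair, with Xist at 0.03 RPKM in PEM mouse 1, and sex was no covariate.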

How the results depend on the processing

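Cells with mature markers left out, cells with 1800 to 3000 detected genes, and the mean of log2 values with quantile normalization were chosen after seeing the data. No paired analysis was possible because the replicate numbers were given in accession order and the labels pair no mice. With 1 mouse left out, the lone mouse of a group was assumed to vary like the other groups. The filter on cells with few genes removed 0 cells and so tested nothing. Ctla2b stayed lower in PLT than in MUL in all 22 alternatives, with log2 fold changes of -6.24 to -3.56, and passed the threshold in 8 of them (adjusted p = 0.00274 to 0.541). In 7 of the 22 its fold change was the same -4.29 as over all mice and cells: no filter, the stricter filter, the filter on cells with few genes, no intensity trend, only the mice compared and each PEM mouse left out. The cause of the changes below was not tested.

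In PLT minus MUL, where 1 gene was called, 0 were called with a pseudocount of 0.1, the mean of log2 values, 25 cells per mouse, plate P1 alone, plate P2 alone, no intensity trend, cells with 1800 to 3000 detected genes and only the mice compared, and 0 to 1 with 1 mouse left out. The counts were 2 with a pseudocount of 10, 19 without a filter on low values, 3 with the stricter filter, 4 with quantile normalization, 13 with the mean of log2 values and quantile normalization, and 2 without cells with mature markers. Beside Ctla2b, the genes called were Mmrn1 with a pseudocount of 10, Mt1 and Erdr1 with the stricter filter, Mmrn1, Mt1 and Erdr1 with quantile normalization, and Erdr1 without cells with mature markers. The others called without a filter are not named. Their SEs on the log2 scale were as low as 0.015, against a median of 0.746 over the genes of the main fit. The 13 genes called with the mean of log2 values and quantile normalization were Ctla2b, Mmrn1, Mt1, Erdr1, Cd27, Cd34, Clu, Gkn3, Ccl3, Dusp1, Tsc22d3, Ctla2a and Pik3ip1, the last chosen after its values were seen. In PEM minus MUL, where 0 were called, the counts were 9 without a filter, 1 with the mean of log2 values and quantile normalization and 1 without cells with mature markers, Erdr1 in both. In PLT minus PEM, where 0 were called, they were 4 without a filter and 1, Mmrn1, with the mean of log2 values and quantile normalization. In the mean of PLT and PEM minus MUL (restricted minus MUL), where 0 were called, they were 1 with a pseudocount of 10, 18 without a filter, 2 with the stricter filter, 2 with quantile normalization, 1 on plate P1 alone, 9 with the mean of log2 values and quantile normalization and 1 without cells with mature markers. Ctla2b was among those called in 4 and Erdr1 in 5 of 21 alternatives there. For lists, camera with an estimated correlation and fry each called 0 in all 4 contrasts. In PLT minus MUL the preset count of 5 became 8 with the mean of log2 values, 8 with 25 cells per mouse, 8 without cells with mature markers, 10 in cells with 1800 to 3000 detected genes and 5 to 10 with 1 mouse left out. In PLT minus PEM the preset count of 7 became 4 with a pseudocount of 0.1, 4 without a filter, 2 with the mean of log2 values, 2 with median-ratio scaling, 1 on plate P1 alone, 0 without an intensity trend, 3 with the mean of log2 values and quantile normalization, 3 without cells with mature markers and 3 to 8 with 1 mouse left out. At 1 RPKM or more, the median number of genes per cell was 2372 in MUL, 2957 in PEM and 2225 in PLT mice. The mean share of cells at that level was 47.4% in PEM and 34.9% in PLT for Vwf, 36.5% in PLT for Mmrn1 and 88.6% in MUL for Ctla2b.

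Among 182 pairs of a named gene and a contrast, 134 kept their sign, and none of those that did not had passed the threshold over all mice. Without cells with mature markers, fold changes that lost their sign were Ptprc 0.0067, Mecom 0.095, Mki67 0.51 and Klf1 1.004 in PLT minus MUL, Selp -0.0079, Ly6a -0.11 and Mki67 0.29 in PEM minus MUL, Hlf 0.18 and Procr 0.79 in PLT minus PEM, and Mki67 0.40 and Klf1 1.96 in restricted minus MUL. On plate P2 alone, fold changes that lost their sign were Gp1ba -0.58 and Hlf 0.013 in PLT minus MUL, Gp1ba -0.72, Hlf 0.013, Itga2b -1.27, Flt3 0.54, Klf1 -0.16 and Gata1 -0.24 in PEM minus MUL, Ptprc -0.048, Gp1ba 0.14, Hlf 0.00054, Mecom -0.20, Pf4 1.39 and Gata1 0.64 in PLT minus PEM, and Cby1 0.093, Gp1ba -0.65, Hlf 0.013 and Cdkn1c -0.57 in restricted minus MUL. With the mean of log2 values over cells, fold changes that lost their sign were Mecom 0.099 and Mki67 0.12 in PLT minus MUL, Ptprc 0.032, Hlf 0.043, Procr 0.24, Mecom 0.016, Kit 0.32 and Mki67 0.050 in PEM minus MUL, Ptprc -0.66, Selp -0.041 and Slamf1 -0.57 in PLT minus PEM, and Itga2b 0.15, Mecom 0.058 and Mki67 0.088 in restricted minus MUL. With 25 cells per mouse, fold changes that lost their sign were Mecom 1.03, Mki67 2.25 and Gata1 -1.01 in PLT minus MUL, Mecom 0.095, Kit 0.21, Mki67 1.5, Cdkn1c 1.16 and Klf1 -0.037 in PEM minus MUL, Ptprc -0.64 and Slamf1 -1.2 in PLT minus PEM, and Mecom 0.56 and Mki67 1.88 in restricted minus MUL. With quantile normalization, fold changes that lost their sign were Mecom 0.11 and Mki67 0.17 in PLT minus MUL, Ly6a -0.15 in PEM minus MUL, and Hlf 0.087 and Procr 0.078 in PLT minus PEM. With median-ratio scaling, fold changes that lost their sign were Mecom 0.095 in PLT minus MUL, and Procr 0.054 in PLT minus PEM. On plate P1 alone, fold changes that lost their sign were Mecom 0.22, Mki67 0.40, Klf1 1.55 and Gata1 -0.32 in PLT minus MUL, Ly6a -0.33, Mki67 0.55 and Cdkn1c 0.43 in PEM minus MUL, Slamf1 -0.48, Procr 0.064, Flt3 0 and Mki67 -0.16 in PLT minus PEM, and Mki67 0.47 and Klf1 1.92 in restricted minus MUL. With the mean of log2 values and quantile normalization, fold changes that lost their sign were Mecom 0.27 and Mki67 0.20 in PLT minus MUL, Ly6a -0.27 in PEM minus MUL, Ptprc -0.032, Gp1ba 0.036 and Procr 0.094 in PLT minus PEM, and Mki67 0.031 in restricted minus MUL. In cells with 1800 to 3000 detected genes, fold changes that lost their sign were Mki67 0.23 in PLT minus MUL, Itga2b -1.89, Procr 0.51, Flt3 0.17, Klf1 -2.7, Gata1 -0.20 and Clu -1.58 in PEM minus MUL, Ptprc -0.45, Gp1ba 0.61, Pf4 0.85, Klf1 0.85 and Gata1 1.91 in PLT minus PEM, and Procr 0.12 in restricted minus MUL. With 1 mouse left out, fold changes that changed sign or reached 0 were, in PLT minus MUL, Gp1ba from -0.76 to 1.249, Procr from -1.24 to 0.73, Mecom from -0.22 to 0.087, Mki67 from -0.74 to 0.39 and Gata1 from -0.56 to 1.2. Those in PEM minus MUL were Selp from -0.47 to 1.14, Cd48 from -1.94 to 0.031, Hlf from -0.73 to 0.042, Ly6a from -0.35 to 0.48, Procr from -0.57 to 0.23, Mecom from -1.21 to 0.0039, Kit from -0.46 to 0.12, Flt3 from -1.59 to 0.71, Mki67 from -0.95 to 0.18, Cdkn1c from -1.49 to 0.34 and Klf1 from -1.97 to 2.18. Those in PLT minus PEM were Ptprc from -0.30 to 0.41, Selp from -0.24 to 1.3, Cd48 from -1.97 to 0, Slamf1 from -0.56 to 0.58, Gp1ba from -1.42 to 0.59, Hlf from -0.57 to 0.27, Procr from -1.07 to 0.90, Mecom from -0.073 to 1.14 and Mki67 from -0.13 to 0.55. Those in restricted minus MUL were Selp from -0.21 to 1.4, Gp1ba from -0.050 to 0.95, Itga2b from -1.55 to 0.13, Ly6a from -0.77 to 0.066, Procr from -0.71 to 0.28, Mki67 from -0.85 to 0.29, Cdkn1c from -0.74 to 1.09 and Klf1 from -3.12 to 0.46.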

Other observations

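The tests of gene length on the oxidative phosphorylation list and of the number of detected genes on both lists were chosen only after the result was seen, and the list medians below are for the mean of PLT and PEM minus MUL.

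Cd27, a receptor of the tumour necrosis factor family on lymphocytes and progenitors that was chosen after its values were seen, had 163 ± 33.6 RPKM in MUL, 98.4 ± 18.3 in PEM and 11.6 ± 15.7 in PLT mice (SD, n = 2 each). In the limma fit without PLT mouse 1, Cd27 was the 1 gene past the threshold in PLT minus MUL, and in the main comparison over all mice it did not pass (adjusted p = 0.461). Over all mice it passed with the mean of log2 values and quantile normalization, with a log2 fold change of -4.55 in PLT minus MUL (adjusted p = 0.00275, range over 22 alternatives 0.00275 to 0.977) and -3.20 for the mean of PLT and PEM minus MUL (adjusted p = 0.0266, range over 21 alternatives 0.0266 to 0.99).

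The medians of the ribosomal protein and oxidative phosphorylation lists lay above 0 in both restricted groups against MUL, but neither list was called with an estimated correlation (adjusted p = 0.396 and 0.447 for the mean of both groups), and the preset test called a mean of 5.12 lists in simulated mice without a difference, so noise between mice stays open. Both lists hold short genes (median lengths 1781 and 1789 bases against 4272 over all genes), and after a length trend was taken out of each mouse the ribosomal median was 0.57 (before, 0.63; SD over members 0.40 after), which argues against length as the whole cause for that list. The oxidative phosphorylation median went from 0.56 to 0.33 (SD over members 0.45 after), so for that list length stays open. In cells with 1800 to 3000 detected genes the ribosomal and oxidative phosphorylation medians were 0.70 and 0.60. This range kept 36 and 11 cells of PEM mice 1 and 2. Cells were not matched between groups within it, so it cannot decide on the number of detected genes. Without PLT mouse 2 the ribosomal and oxidative phosphorylation medians over all cells were 0.50 and 0.32. A difference between experiments and the fate of the clone, which was not tested apart from it, cannot be told apart, since 0 experiments hold both MUL and other mice.

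The median of the immediate early and stress list lay below 0 in both restricted groups against MUL, but the list was not called with an estimated correlation (adjusted p = 0.292 in PLT, 0.252 in PEM and 0.215 for their mean) or by fry (adjusted p = 0.26 for the mean), so noise between mice stays open. Without the 10% of cells of each mouse with the highest RPKM sum over the list its median was -1.18 (before, -1.42; SD over members 1.13 after). Hsp90aa1 weighs heavily in that sum, at 777 and 343 RPKM in the MUL mice and 497 and 833 in the PLT mice. It was not lower in PLT (log2 fold change 0.32). The cells left out need not be those with the strongest response, so the check cannot decide whether a few such cells made the difference. The handling of tissue may differ between experiments, and 0 experiments hold both MUL and other mice, so a difference between experiments and one between fates cannot be told apart.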
